A study of Oryza sativa with 12 samples.

How the data were processed

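RNA was extracted from rice abscission zones on the day of flowering, from 3 replicates of 5 pooled plants in each of 4 groups, per the labels. Plants grew in the field at one of 2 named places, and the labels do not tie samples to places. Libraries were prepared with an mRNA-seq kit and sequenced on a BGISEQ instrument, per the labels. HISAT2, RSEM 1.3.1, DESeq2 and the build IRGSP-1.0 are named in the submitters' processing notes, with no role or order given; whether counting used strand is not given in the sources used here.

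The authors deposited one table per comparison. The ossh1 table holds whole-number read counts, per the file headers and its values, for 55986 IDs, of which 17923 were at 0 in all 6 libraries. The oscct table holds estimated counts, deposited as read counts per the file headers, with 58.5% of the values whole. It has 13301 rows for 11688 distinct IDs, 10473 listed 1 time and 1215 in several rows, with 10 exact repeats, and all 11688 IDs are in the ossh1 table. It lacks rows with small group differences: the empty range was 0.64 log2 units wide in the lowest class of mean counts examined and 0.14 in the highest. The step that removed these rows is not given in the sources used here, and the library depth behind this table is unknown. How rows of one ID differ is not stated either; shared reads between them or between gene copies could be split by the estimation, so single rows at 0 are uncertain.

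Estimated counts were rounded to whole numbers. Each mutant was compared with its own control in edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment and a threshold of 0.05, with no replicate block. Calls in the oscct table were made on rows selected for a difference, so their error rate has no usual meaning there. The difference between mutants was tested over the 10473 IDs listed 1 time, with scaling factors from each full table, of which 10439 passed the filter. Overlap used Fisher's exact test of direction among IDs past both tests and the counts of independent lists. A fold against a group at 0 was set against 3 counts over that group; intervals and floors cover counting error only. Replicates are pools of separate plants per the labels. The common biological coefficient of variation was 4.3% in the ossh1 table and 4.4% in the oscct table.

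The reference table of gene names is of another assembly and paired 1 ID with a name, so IDs are given as in the files and gene lists fixed before the data were examined (lignin, shattering, secondary wall, floral, anther, clock and described families) matched no ID and were not tested. Markers of other tissues in the dissected zone were part of those lists and were likewise not analysed. The rule for named genes had asked for the genes of the title, list members, the 8 largest rises and falls with a name and genes shared by both comparisons. With names missing, only its part on the largest changes was kept, without the condition on names and reduced to 2 rises and 2 falls per comparison: the largest log2 fold changes with an adjusted p under 0.05, no overlap between groups and a mean log2 CPM of at least 1. The 1 named ID was added after the values were seen.

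Chosen after seeing the data were the regions, the repeated IDs, the comparison by presence in the oscct table, the splits by abundance and chromosome, the scaling to the centre of the empty range, the whole-number subset and the summed rows. Windows of 20 tested IDs were scanned by the count of changes of at least 2-fold, using the most abundant row of an ID, with 1000 shuffles of the changes over positions. Windows of 10 and 40 were added later with 200 shuffles, which can give no permutation p under 0.005. Alternatives were the replicate block, RLE, library totals, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom (limma 3.58.1), other thresholds, one fit of all libraries and each library left out. The procedures were tested on simulated data with 200 changed genes each, drawn from genes with a mean of at least 50 counts. All simulated genes had the same biological spread, and far fewer changed than were called in the real data. The rates below therefore need not hold for genes with lower counts or for rows selected for a difference. In ossh1 (22417 genes) 98% of 1.5-fold and 100% of 2-fold changes were recovered, with 11 false calls among 22217 unchanged genes. In oscct (12974 rows) these were 94% and 100%, with 8 false calls among 12774. For the difference (10407 IDs) 93.5% of 2-fold changes were recovered, with 7 false calls among 10207. Figures were drawn with matplotlib 3.10.9.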

Results

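Gene expression was measured by RNA sequencing in the abscission zone of rice, the layer of cells between the pedicel and the spikelet where the grain separates from the plant, on the day of flowering. The 12 libraries fell into 4 groups of 3: the mutant ossh1 and its wild type WT, and the mutant oscct and its wild type CK. Each library was made from a pool of 5 plants, per the labels. The series title places OsCCT22, OsSh1 and OsCAD2 in one module that acts on seed shattering through lignin synthesis, and each mutant was sequenced beside a control group of its own. The WT libraries held from 30382846 to 32055561 counts and the ossh1 libraries from 27044341 to 28600944. The values listed for CK summed to between 12943437 and 13318397 per library and those for oscct to between 12526152 and 12812857, but the oscct table holds only part of each library, so these sums are not its depth. Replicates of one group differed by more than sampling noise, with a chi-square per degree of freedom from 2.2 to 4.29 over all pairs. The files name genes by locus IDs and do not pair them with names, so OsSh1, OsCCT22 and OsCAD2 were not analysed here, and the state of the targeted gene in each mutant was not checked.

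The comparison of ossh1 with WT asked which genes differ in the abscission zone between the mutant and its wild type. LOC_Os01g06050 on chromosome 1 had 0 counts in all 3 WT libraries and 629, 560 and 658 counts in the ossh1 libraries, at least 743-fold higher in ossh1. LOC_Os03g20200 on chromosome 3 also had 0 counts in WT and 447, 412 and 472 counts in ossh1, at least 535-fold higher. Both bounds set the mutant against 3 counts over the 3 WT libraries together. In the other direction, LOC_Os09g36680 on chromosome 9 fell from 155 ± 3.14 CPM (scaled read counts; SD, n = 3) in WT to 1.03 ± 0.394 CPM in ossh1. Its log2 fold change was -7.23 (SE 0.09, adjusted p = 5.22e-43, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). LOC_Os10g37020 on chromosome 10 fell from 61.5 ± 1.71 to 0.903 ± 0.213 CPM (SD, n = 3), a log2 fold change of -6.09 (SE 0.1, adjusted p = 1.95e-37, same edgeR test).

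LOC_Os01g19850 was the only ID with a name in the reference table, where it carries the synonyms KCC2 and OsCCC2, names used for a cation-chloride cotransporter. It was at 7.06 ± 0.297 CPM in WT and 4.33 ± 0.988 CPM in ossh1 (SD, n = 3). The fall had a log2 fold change of -0.71 (SE 0.14, adjusted p = 4.16e-05, edgeR). This gene was not in the oscct table.

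Differences between ossh1 and WT were broad. Of 22669 genes tested, 13220 (58.3%) passed an adjusted p of 0.05 in edgeR, 6629 higher and 6591 lower in ossh1. The test sets the groups against the spread among 3 pools in each. Line background and growing place could not be separated from the mutation, so the count is not one of genes changed by it. The median log2 fold change was 0.54 among the higher genes and -0.5 among the lower ones. A change of at least 2-fold was found for 1810 higher and 1125 lower genes, and one of at least 8-fold for 230 higher and 83 lower genes. The 3 libraries of one group did not overlap with those of the other in 62.3% of the tested genes, against 10% by chance. There were 18 genes at 0 in every WT library with at least 20 counts in every ossh1 library, and 2 genes with the opposite pattern. The 18 genes lay on 10 chromosomes, with 5 on chromosome 1, and their mean counts in ossh1 ran from 28.7 to 615.7. Scaling by library totals alone gave 5257 higher and 8364 lower genes, 38.6% higher instead of 50.1%, and moved the median log2 fold change of all tested genes from -0.012 to -0.108, so small changes depend on the scaling.

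**Figure D1:**
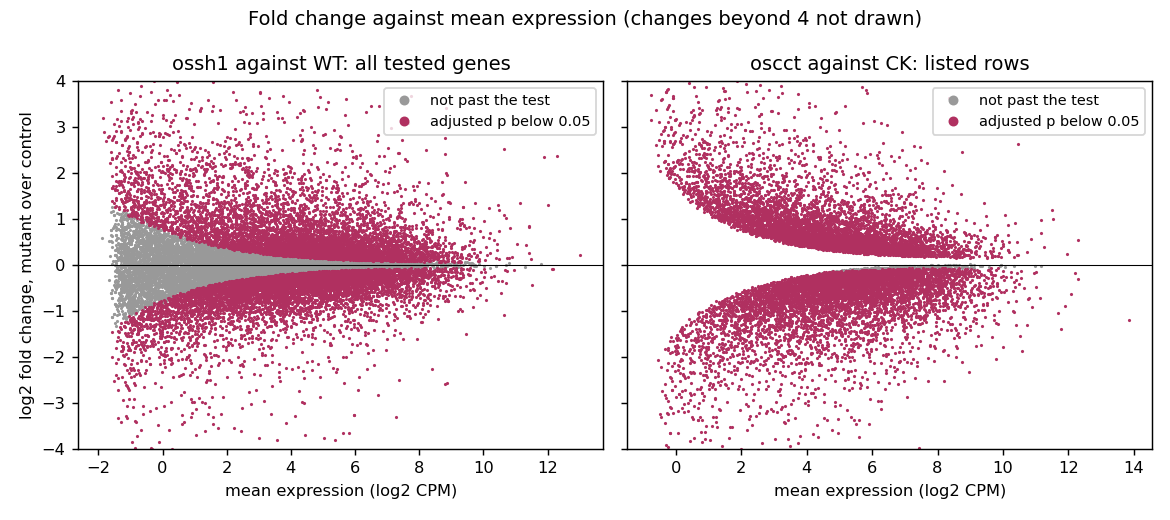
Log2 fold change of mutant over control (vertical axis) against mean expression in log2 CPM (horizontal axis), one point per tested gene for ossh1 against WT (left) and per tested row for oscct against CK (right), red where the adjusted p was below 0.05; changes beyond 4 on the log2 scale are not drawn. On the left 13220 of 22669 genes passed the test and points fill the range around 0; on the right 12671 of 13066 rows passed and a range that narrows with expression is empty.

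Genes with a change of at least 2-fold in ossh1 lay on all 12 chromosomes. In 4 windows of neighbouring genes, their count in one direction exceeded that of the fullest window in most shuffles of positions. The highest count in any shuffle was 11 for rises and 9 for falls. Positions are the chromosome and serial number within the locus IDs, which follow gene order along the chromosome by the naming convention. On chromosome 9, from serial number 36550 to 36820, 10 of 20 neighbouring tested genes were at least 2-fold lower in ossh1 and 1 was at least 2-fold higher, with a median log2 fold change of -0.87 (SD 1.83 over genes). LOC_Os09g36680 lies in this region. A second region on chromosome 9, from 37310 to 37620, held 9 such lower genes of 20 and 1 at least 2-fold higher (median -0.82, SD 0.98). On chromosome 12, from 33280 to 34128, 12 of 20 neighbours were at least 2-fold higher (median 1.24, SD 0.91), and on chromosome 7, from 3600 to 3970, it was 10 of 20 (median 1, SD 1.07). Each count was set against the fullest window of the genome in 1000 shuffles of the changes over gene positions. The permutation p was 0.001 for chromosome 12, 0.011 for chromosome 7, 0.001 for the first chromosome 9 region and 0.002 for the second. The smallest p these shuffles can give is 0.001. They place genes independently, but adjacent genes were alike over the genome (Spearman correlation 0.11). These p-values can therefore be too small and do not set the regions apart from that general likeness. The best window of each direction had an adjusted p of 0.002 over the 4 searches made. With genes under a mean of 1 CPM left out, the chromosome 12 region held 5 genes of at least 2-fold change and the second chromosome 9 region 2. Most of the 2-fold changes counted in these 2 regions therefore rest on genes with low counts.

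The comparison of oscct with CK asked the same of the oscct mutant. LOC_Os03g02470 on chromosome 3 was listed in 3 rows, all at 0 in the 3 CK libraries. Its most abundant row had 3408, 3275 and 3228 counts in oscct, at least 3137-fold higher. LOC_Os06g15430 on chromosome 6 had 0 counts in CK and 351, 376 and 355 in oscct, at least 342-fold higher. Among falls, 1 row of LOC_Os01g12710 on chromosome 1 had 178, 296 and 174 counts in CK and 0 in all oscct libraries, at least 227-fold lower. The other row of this ID, which carried most of its counts, had 4570, 4274 and 4551 in CK and 2501, 2442 and 2684 in oscct, and the summed rows of this ID had a log2 fold change of -0.99 (SE 0.03). One row of LOC_Os08g34060 on chromosome 8 had 233, 105 and 82 counts in CK and 0 in oscct, at least 147-fold lower, while its remaining 2 rows had more counts in every oscct library than in any CK library. With its rows summed, LOC_Os08g34060 was higher in oscct, with a log2 fold change of 0.26 (SE 0.04, adjusted p = 3.56e-06, edgeR), so the fall is that of the single row. For LOC_Os01g12710 and LOC_Os08g34060, the estimated counts of the rows, before rounding, add up to whole numbers in every library. Reads therefore appear to have been divided among rows of the same ID, and the bounds on these falls do not cover errors of that division.

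The table lists only rows chosen for a difference between the groups. Among its 3193 rows with a mean of at least 1000 counts, 0 lay within 0.05 log2 units of the centre of the empty range of group differences. In the ossh1 table, 711 of 6069 such genes (11.7%) lay that close to the median difference of these 6069 genes. Calls in the oscct table are therefore circular and count the rows listed, not the genes that changed. Of 13066 rows tested, 12671 passed the test, 6130 higher and 6541 lower in oscct. This balance turned with the scaling, to 6234 higher and 5234 lower rows by listed totals and 6134 and 5956 with RLE scaling, and to 6127 and 5332 with DESeq2. A change of at least 2-fold was found for 1972 higher and 1783 lower rows, and one of at least 8-fold for 195 higher and 155 lower rows. There were 18 rows at 0 in every CK library with at least 20 counts in every oscct library, and 8 with the opposite pattern. The median log2 fold change of the rows tested was -0.114 with the main scaling, 0.018 with the listed totals and -0.198 when centred on the empty range, so directions near 0 depend on the scaling.

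Many IDs had several rows in the oscct table, up to 10. Of 1135 IDs with at least 2 rows past the test, 357 rose in all these rows, 680 fell in all of them, and 98 (8.6%) had rows in opposite directions. Shuffling the directions over rows put 56.4% of these IDs in opposite directions on average, and at the lowest 51.7%. Only 5 of the 98 had opposite changes that were both at least 2-fold.

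In oscct, the fullest window of listed rises lay on chromosome 2. From serial number 35870 to 36414, 12 of 20 neighbouring listed IDs were at least 2-fold higher in oscct and 1 was at least 2-fold lower, with a median log2 fold change of 1.36 (SD 1.58 over IDs). The permutation p was 0.024, and 0.032 when adjusted over the 4 searches, but the call was lost with windows of 40 IDs (permutation p = 0.16 for the fullest window, which overlaps this stretch). The search for listed falls in oscct found no window of 20 past the threshold (permutation p = 0.11). With windows of 40 it found a window on chromosome 6, from 13080 to 15600, with 15 IDs at least 2-fold lower (permutation p = 0.04, not adjusted). These shuffles carry the limit given for ossh1, because adjacent listed IDs were also alike (Spearman correlation 0.128). In ossh1 the chromosome 2 stretch from 35870 to 36414 held 29 tested genes, of which 15 were higher, 4 lower and 10 not past the test, and 8 were at least 2-fold higher. The regions found in ossh1 were read in oscct likewise. All 5 listed IDs of the chromosome 12 region and all 8 of the chromosome 7 region were higher in oscct, with median log2 fold changes of 2.29 (SD 0.56) and 1.38 (SD 1.3). In the first chromosome 9 region, lower in ossh1, 7 listed IDs were higher in oscct and 2 lower, and in the second 4 were higher and 1 lower. Each median was ranked by its distance from the median of all IDs. The ranking was against randomly drawn stretches of as many neighbours in the same comparison, which can overlap. The adjusted p of this ranking over the 5 readings was 0.0125 for chromosomes 12 and 7, 0.2 and 0.025 for the first and second chromosome 9 regions, and 0.025 for chromosome 2.

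**Figure D2:**
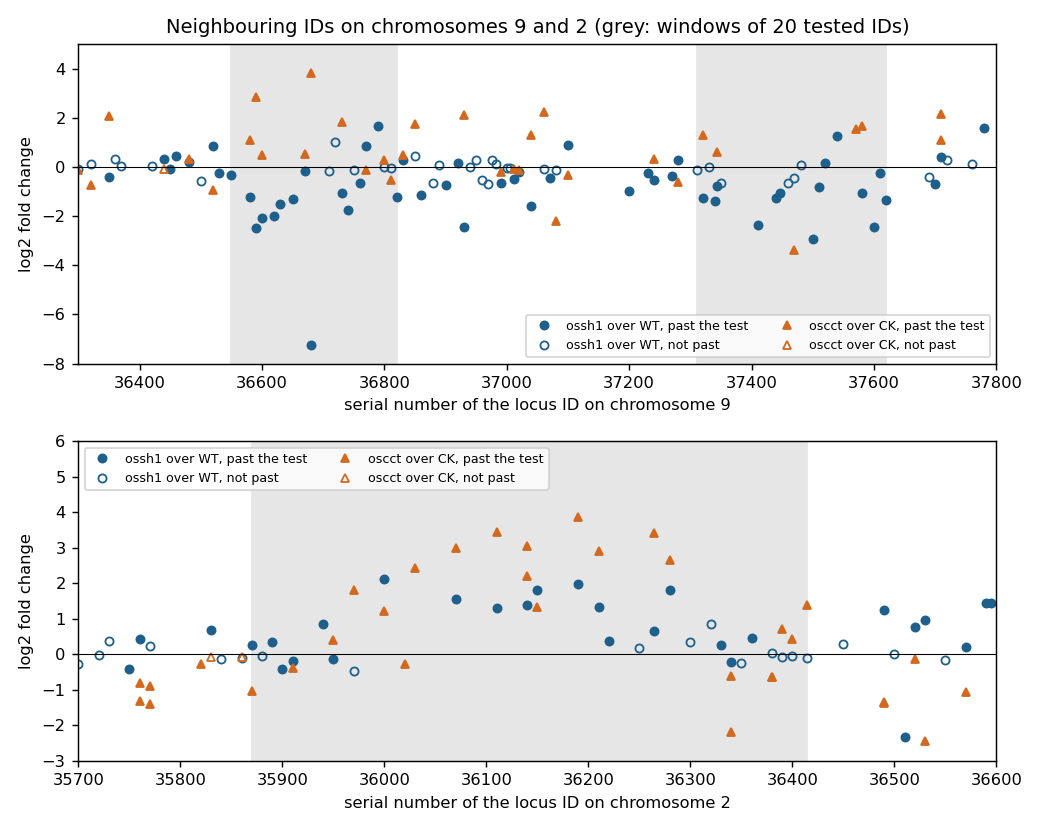
Log2 fold change (vertical axis) of neighbouring IDs by their serial number (horizontal axis) on chromosome 9 (top) and chromosome 2 (bottom), with circles for ossh1 over WT and triangles for oscct over CK, filled where the adjusted p was below 0.05; grey marks the windows of 20 tested IDs. In the first chromosome 9 window 10 of 20 genes were at least 2-fold lower in ossh1, and in the chromosome 2 window 12 of 20 listed IDs were at least 2-fold higher in oscct.

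The mutants were then set side by side, with no control library in common. Over the 9566 IDs listed 1 time in the oscct table and tested in both comparisons, 6264 passed both tests, and 2388 of these (38.1%) changed in the same direction. Both mutants were higher for 1197 IDs, where independent lists would give 1652, and both lower for 1191, where they would give 1471. Higher in oscct and lower in ossh1 were 1939 IDs (1621 for independent lists), and lower in oscct and higher in ossh1 were 1937 (1499). The odds ratio of direction was 0.38 (95% interval 0.342 to 0.421, two-sided Fisher's exact p = 1.52e-79), a value over genes, which are not independent replicates. Across genes, the log2 fold changes had a Pearson correlation of -0.124 and a Spearman correlation of -0.17. Among the 625 IDs with a change of at least 2-fold in both, 181 rose in both mutants, 91 fell in both, 103 rose in oscct and fell in ossh1, and 250 fell in oscct and rose in ossh1. All 4 of these counts exceeded those of independent lists, which were 114, 38, 53 and 82. Over all IDs past both tests, overlaps in the same direction were instead fewer. The odds ratio of direction among the 625 IDs was 0.64 (95% interval 0.448 to 0.913, two-sided Fisher's exact p = 0.0117, over genes), so opposite directions still prevailed.

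**Figure D3:**
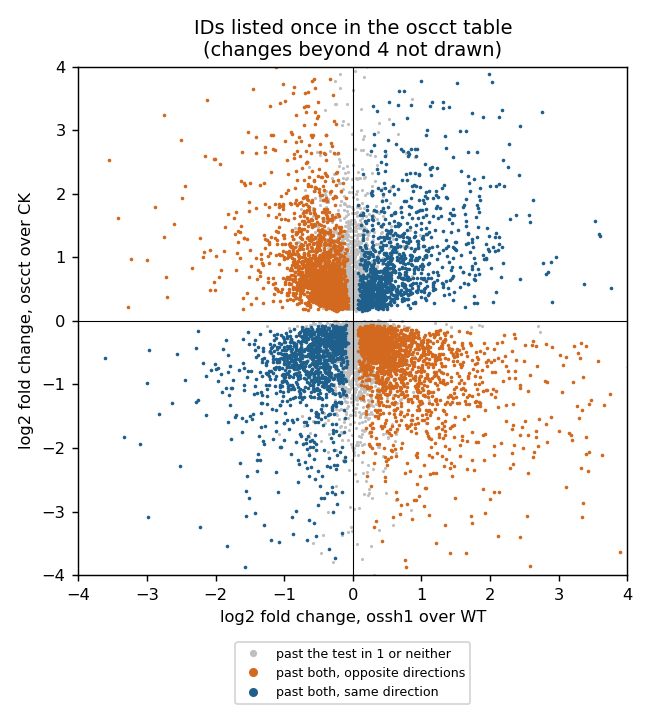
Log2 fold change of oscct over CK (vertical axis) against that of ossh1 over WT (horizontal axis), one point per ID listed 1 time in the oscct table; changes beyond 4 are not drawn. Of 6264 IDs past both tests, 2388 changed in the same direction (blue) and the others in opposite directions (orange).

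Genes in the oscct table also changed more often in ossh1. Of 10826 tested genes with a row in that table, 68.4% passed the test in ossh1, against 49.1% of 11843 genes with no row. With genes split into 5 classes of abundance, the common odds ratio was 1.5, with a 95% interval of 1.41 to 1.59 (Mantel-Haenszel test over genes). In each class the share was higher among listed genes, 42.8% against 32.7% in the least abundant class and 81.3% against 74.9% in the most abundant one. Listing rose with abundance, from 870 genes listed and 3664 not in the least abundant class to 3261 and 1273 in the most abundant. Abundance also varies within a class, so the 5 classes need not remove all of its effect.

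The difference between the mutants was tested directly in one model of all 12 libraries. Of 10439 IDs, 8342 (79.9%) had a change that differed between oscct and ossh1 at an adjusted p of 0.05, 3633 of them by at least 2-fold, and 4079 changed in opposite directions with each change past its own test. LOC_Os09g36680 rose in oscct with a log2 fold change of 3.81 and fell in ossh1 with one of -7.23, a difference of 11.04 (SE 0.12, adjusted p = 1.54e-28, edgeR). It was chosen for its fall in ossh1 and was listed for a difference in oscct, so this p-value has no usual meaning. Because IDs entered this test only if listed for oscct, the share is not one of all genes.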

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

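All tests of explanations below were chosen after the result was seen, and so were the regions and the comparison of repeated IDs; the difference between the mutants was planned before the data were examined.

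The change differed between oscct and ossh1 for 8342 IDs by the test of the difference itself. LOC_Os09g36680, named above for its fall in ossh1, was among them, with oscct 11.04 log2 units above ossh1. The differences of the other IDs were not ranked against it. Of 100 splits of the 12 libraries drawn from those within each table, the real one was the only 1 with as many calls, and the highest of the others gave 5706. This count does not bear on chance, because the IDs come from a table whose rows were selected under the real grouping of oscct and CK. The splits that called many IDs kept the real grouping of one table, which is a structure of the samples.

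IDs past both tests mostly changed in opposite directions in the 2 mutants. Among IDs with whole numbers in the oscct table, 37.8% went the same way. This share cannot decide whether rows for single transcripts were set against whole genes. A single transcript that shares no reads also has whole numbers, so that explanation stays open. A trend with abundance is argued against, because the highest share over 5 classes of abundance was 41.6%. Centring the oscct table on its empty range left the share at 38.1%, and RLE scaling gave 38.6%. The centring kept 100% of the calls in oscct, with 0 changes of sign. It moves the zero point to where rows were removed, so a share that stays the same cannot decide on the scaling. The share was not computed with library totals, and the scaling stays open. Transcript length, RNA quality, exact stage, growing place and line background stay open and untested, as does an effect of the genotypes, and the labels tie no library to one of the growing places.

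Genes silent in WT and present in ossh1 numbered 18. Lower depth in WT is argued against, since the mean WT total was 1.13 times that of ossh1. A single foreign segment in the mutant line is argued against, because at most 5 of the 18 lay on one chromosome. Different line backgrounds of ossh1 and WT over many segments may still account for them and were not tested, and so may the mutation itself.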

How the results depend on the processing

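The empty-range scaling, the summing of rows, the subset of whole-number IDs and all settings for the regions were chosen after seeing the data. With the rows of one ID summed, LOC_Os08g34060 turned from a fall in 1 row to a rise in oscct (log2 fold change 0.26), because its other rows rose; no other named ID changed direction under the alternatives run. A change of at least 2-fold left 2935 genes in ossh1 (1810 higher, 1125 lower) and 3755 rows in oscct (1972 and 1783), by construction. One fit of all 12 libraries gave 6849 genes in ossh1 (3461 higher, 3388 lower) and 10053 in oscct (5274 higher, 4779 lower), because only 10439 IDs entered; the fit of ossh1 and WT alone gave 6516 among 9657 of these, and that of oscct and CK alone 9958 among 10303 (5206 higher, 4752 lower). Leaving out each library in turn gave 12250 to 12750 genes in ossh1 (6200 to 6425 higher, 6023 to 6331 lower), 12383 to 12527 rows in oscct (6139 to 6174 higher, 6209 to 6378 lower) and 8160 to 8227 IDs for the difference between mutants. Same-numbered libraries did not deviate together (correlations from -0.067 to 0), and no control library correlated best with its own number; with the replicate block, 12971 genes in ossh1, 12590 rows in oscct and 8257 IDs for the difference passed. RLE, DESeq2 and limma-voom gave 13197, 12223 and 13216 genes in ossh1 and 12090, 11459 and 12655 rows in oscct. The balance in oscct turned from more lower to more higher rows with RLE (6134 higher, 5956 lower), DESeq2 (6127, 5332) and library totals (6234, 5234). It also turned at changes of at least 2-fold and at an adjusted p under 0.01 (6118, 5807). The fit of all libraries had more higher than lower IDs too. So did the fit of oscct and CK alone among the same IDs (5206, 4752), so that turn comes with the IDs that entered. At changes of at least 2-fold in both mutants, overlaps in the same direction turned from fewer to more than independent lists give (181 against 114 higher, 91 against 38 lower). Overlaps in opposite directions also exceeded them (103 against 53 and 250 against 82). The share in the same direction was 43.5% against 38.1%, and the odds ratio of direction was 0.64 against 0.38, below 1 at both settings. The causes were not tested. The 10 splits of 6 libraries allow no share under 0.1: in each comparison 1 split gave as many calls, the real one with 13220 in ossh1 and 12671 in oscct, and the highest other gave 0. The chromosome 2 region had a permutation p of 0.005 with windows of 10 IDs, the smallest those shuffles can give, and lost its call with windows of 40 (0.16). A count of 0 in a library allows up to 0.09 to 0.11 CPM in the ossh1 table; depth in oscct is unknown. Pseudocount settings, value filters, gene lists and the genes of the title were not run, since the tables hold counts and the IDs carry no names.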

Other observations

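Fold changes of neighbouring genes were alike beyond chance in both comparisons, a pattern looked for after seeing the data. The Spearman correlation over adjacent tested IDs was 0.11 in ossh1 and 0.128 in oscct, against highest values of 0.022 and 0.032 in 1000 shuffles within chromosomes (permutation p = 0.001 for each, the smallest these can give). Between IDs 2 places apart it was 0.039 and 0.041. The share of listed IDs at least 2-fold higher in oscct was 19.8% on chromosome 10 and 19.3% on chromosome 11, against 12.9% on chromosome 3. In ossh1 it was 10.1% on chromosome 11 and 6.4% on chromosome 3. These shares were not tested.

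The 2 genes silent in every ossh1 library and present in every WT library lay on chromosomes 2 and 11, with mean WT counts of 34.3 and 41. The share of IDs that changed in the same direction in both mutants ran from 34.4% on chromosome 7 to 40.6% on chromosome 4.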
